A study of Mus musculus with 16 samples.

How the data were processed

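RNA of 16 cultures of mouse ES cells, EpiSC, EpiSC-like lines and iPS lines was measured on Agilent mouse arrays (design 014868, grid build mm7). Per the labels' protocols, ES cells were freed of embryonic fibroblasts by preplating on gelatin, EpiSC and EpiSC-like colonies were separated mechanically, and 0.5 µg of total RNA was labelled with Cy3. Per the file headers, spot intensities were extracted with Feature Extraction 10.1.1.1. The processed signal is an intensity that this software background-subtracted and detrended within the array, with surrogate values for spots not above background and no scaling between arrays, per the file headers. The submitters' processing notes name limma without settings. The deposited value table holds log2 values. From the values, each of its columns ranks the features as the mean spot signal of the same array does and has the same quartiles as every other column (median 6.93), so it is log2 of the mean spot signal after quantile normalization without background correction. Every column of the table was matched to an array.

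Each array held 45018 features, of which 43379 were gene spots and 1639 control spots. Control spots were removed, spots that the extraction software marked as outliers were set to missing, and spots of a probe were averaged. The value analysed was log2 of the processed signal minus the array's 75th percentile. Probes had to be well above background on at least 2 of the 16 arrays, which 34332 of 41174 gene probes were. The probe with the highest mean was taken for each gene, which left 23191 genes (23190 in the epiESM comparison). Gene names came from the RefSeq table supplied with the data, by accession for 22951 probes, by symbol for 6659 and by an older symbol for 3109. The name in the file was kept for 8455. Probe coordinates in the files were not used here, since no genome of that build was at hand. Arrays carry no read depth. The share of gene spots well above background was 63.5% for epiESM, 72.6% for both mESM arrays, 55.9% and 71.7% for EpiSC, 51.2% and 40.5% for EpiSC iPS, and 26.3%, 67.4% and 71.9% for NOD ES. It was 56.8%, 88.5%, 72.9% and 74.7% for EpiSC-like ES replicates 1 to 4 and 69.4% and 65.2% for EpiSC-like iPS.

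The labels gave 7 groups, and limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all 16 arrays with empirical Bayes moderation. In 8 comparisons and 1 interaction, genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed, and "rose" and "fell" are used of these alone. The NOD EpiSC-like mean weighted both lines equally. A gene well above background on no array of one side is given as at least so many fold, against the lowest well-measured signal of each array of that side, and has no fold where both sides were so. Medians of a list "with genes at their bound" use these bounds, with 0 where no fold could be had. Slides were read from the file headers. Slide 1 held iPS line 6 passage 7, EpiSC passage 12 and ES line 1 passage 7, slide 2 the other iPS array, slide 3 EpiSC passage 20 and ES line 1 passage 5. Slide 4 held ES line 1 passage 10, epiESM and NOD ES replicates 2 and 3, slide 5 ES line 1 passage 9 and both mESM arrays, and slide 6 both EpiSC iPS arrays and NOD ES replicate 1. Both mESM arrays carry the same source label and differed with an SD of 0.20, so their spread understates that between cultures if they were 1 culture. An analysis with these arrays averaged is among the alternatives.

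A set of 24 gene lists was fixed before the data were examined, as were the groups, comparisons, tests and most alternatives. They cover the pluripotency core, naive ES markers, primed epiblast markers, mesendoderm, neuroectoderm, trophectoderm, fibroblast feeder cells, LIF-STAT3 targets, Nodal-SMAD2/3 targets, FGF-ERK feedback, WNT targets, germ cell genes, DNA methylation enzymes, antigen presentation, imprinted genes, Y-linked genes, X inactivation, reprogramming factors, 2-cell-stage genes, glycolysis, cytochrome c oxidase, epithelial genes, mesenchymal transition factors and p53 targets. The lists came from general knowledge and some share genes. Lists with at least 3 tested genes were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over all lists and comparisons, which called 77 list and comparison pairs. Counts adjusted over the list alone are given where they differ from those over all genes. With an estimated correlation camera called 0 pairs (26 at an unadjusted p under 0.05), and fry, which does not compare a list with other genes, called 84. L1td1, Prdm14, Fgf4, Dusp5, Rtl1 and Gapdh, among others, had no tested probe.

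Named genes followed a fixed rule. In each comparison these were any gene of the core, naive, primed, reprogramming, fibroblast, X inactivation and Y-linked lists, and up to 4 members of every other list with the largest log2 difference, called ones first. Added were the 6 genes that rose and the 6 that fell most in the first 3 comparisons, and 3 and 3 in the others, with a symbol that is no clone name and with no overlap between the arrays of both sides. Positions are projections of each array on the line between a pair of group means, compared by an exact permutation test.

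Alternatives changed 1 choice at a time. They were quantile normalization, normexp background correction (offset 50), the deposited value table, the mean of all probes of a gene, no filter, a filter on all 16 arrays, trended and robust moderation, array weights, only the arrays compared, the slide as a fixed block, a single EpiSC-like line, both 129 cultures as 1 group, an adjusted p under 0.01, and each array left out in turn. Added after the data were seen were leaving out both arrays of doubtful label, averaging the mESM arrays and the slide as a random block. Of 22985 simulated genes 50 were seeded per fold. For the NOD states the fit recovered 2%, 24%, 62% and 78% of genes changed 1.5-, 2-, 4- and 8-fold. Of 95 calls 12 were false, above the nominal share. For EpiSC against mESM recovery was 0%, 2%, 44% and 72%, with 5 false calls among 64, and for epiESM 0%, 2%, 24% and 52%. Few changed genes made the cutoff stricter than in the real data, so recovery there may be higher. Camera called all 9 lists shifted by 1 log2 unit at an unadjusted p under 0.05, and 0 of 9 unshifted. The genes varied independently, so the preset inter-gene correlation was not tested.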

Results

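RNA of mouse pluripotent stem cell lines was measured on 16 one-colour Agilent arrays. The lines came from the non-obese diabetic (NOD) strain and from non-NOD mice. Embryonic stem (ES) cells stand for the naive state of the inner cell mass. Epiblast stem cells (EpiSC) stand for the primed state of the later epiblast, and the EpiSC-like lines of NOD mice are named after them. The NOD lines comprised 4 arrays of EpiSC-like ES line 1 (passages 5, 7, 9 and 10), 2 arrays of EpiSC-like induced pluripotent stem (iPS) line 6 (passages 7 and 12) and 3 arrays of ES cells. The non-NOD lines comprised 2 arrays of EpiSC (passages 12 and 20), 2 of iPS lines named after EpiSC (EpiSC iPS), 2 of 129 ES cells labelled mESM and 1 of 129 ES cells labelled epiESM. The meanings of mESM, epiESM and the suffixes of the NOD ES and EpiSC iPS titles are not given in the sources used here. Between 26.3% and 88.5% of the gene spots of an array were well above background. No array held a saturated spot, and the number of arrays limits the precision of every value. The p-values measure only the spread between these arrays and passages, since most groups held 1 line.

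Each array was placed on the line from the 129 mESM mean (0) to the EpiSC mean (1) over 22985 genes, to ask how far the NOD arrays had moved along a path that they did not define. The 6 NOD EpiSC-like arrays lay between 0.680 and 0.9991, with a mean of 0.878. The 3 NOD ES arrays lay at 0.410, 0.207 and 0.210, with a mean of 0.276. The difference of 0.602 had an exact 2-sided permutation p = 0.0119, the smallest that 84 splits allow. Without the 2 arrays of doubtful label described below, the difference was 0.669. On the reverse axis, from NOD ES (0) to the NOD EpiSC-like lines (1), the EpiSC arrays lay at 0.746 and 0.815 with a mean of 0.781. The mESM arrays lay at 0.0635 and 0.0619 on that axis, and the epiESM array at 0.171. Without NOD ES replicate 2 the EpiSC mean on this axis was 0.848, and after normexp background correction it was 0.333, so how near EpiSC lay to the NOD EpiSC-like lines depends on the background correction.

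**Figure D1:**
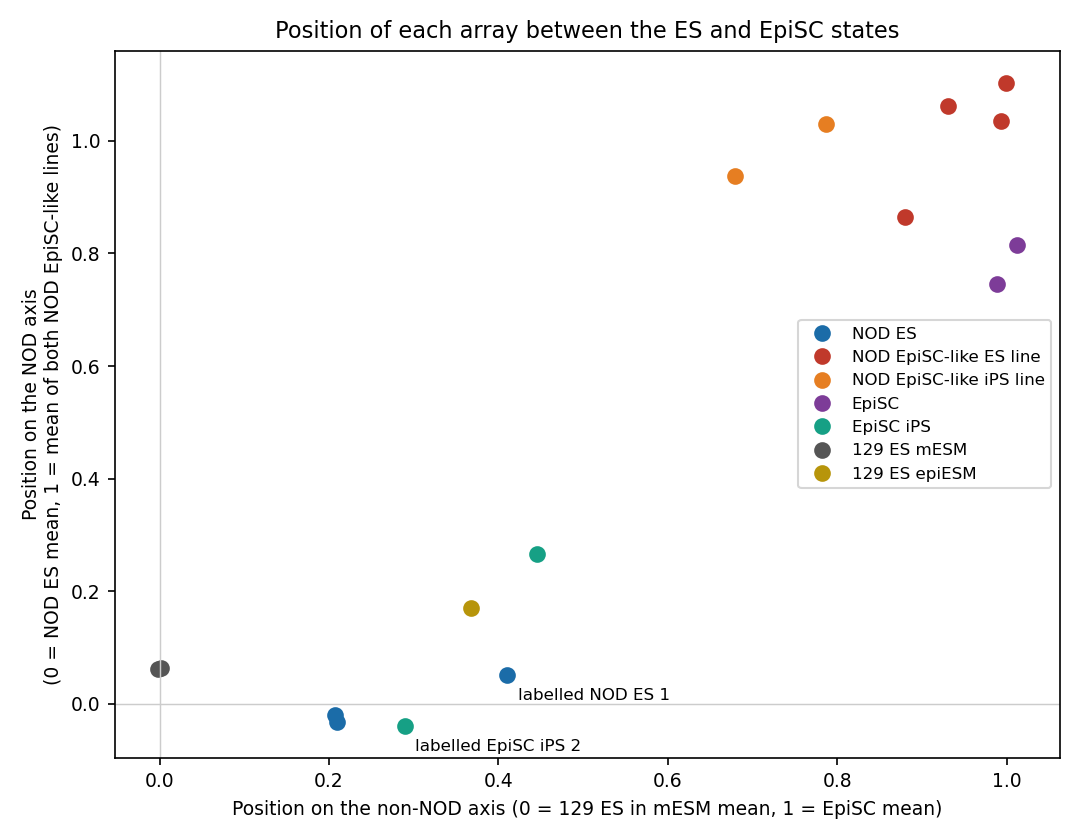
Position of each of the 16 arrays on the axis from 129 mESM (0) to EpiSC (1) and on the axis from NOD ES (0) to the NOD EpiSC-like lines (1), both without units. The NOD EpiSC-like arrays sit between 0.680 and 0.9991 on the first axis, and the NOD ES arrays between 0.207 and 0.410.

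A pair of arrays lay closer to another group than to their own. The array labelled EpiSC iPS replicate 2 differed from NOD ES replicates 2 and 3 with standard deviations (SD) of 0.387 and 0.397 (log2, probes well above background on both arrays), against 0.963 from EpiSC iPS replicate 1. The array labelled NOD ES replicate 1 differed by 0.697 from EpiSC iPS replicate 1, against 1.13 and 1.15 from the other NOD ES arrays. Only 26.3% of the gene spots of the array labelled NOD ES replicate 1 were well above background, and 40.5% of those of the array labelled EpiSC iPS replicate 2. The groups were kept as labelled. Every direction drawn from NOD ES or EpiSC iPS rests partly on these arrays, and leading values are also given without them. These arrays also enter the spread shared by all groups, so they bear on the SEs and calls of every comparison. In comparisons that use neither group, leaving them out changes the calls and not the differences.

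The median difference of all genes depended on the scaling, so every change is relative to it. With each array scaled to its 75th percentile it was -0.27 (log2) for the NOD EpiSC-like lines minus NOD ES, -0.34 for EpiSC minus mESM, 0.42 for EpiSC iPS minus EpiSC, 0.27 for the NOD EpiSC-like lines minus EpiSC, and 0.28 for EpiSC-like iPS minus EpiSC-like ES. It was 0.22 for NOD ES minus mESM, 0.08 for EpiSC iPS minus mESM and -0.02 for epiESM minus mESM. After quantile normalization these medians lay between -0.19 and 0.12. After normexp background correction they lay between -0.03 and 0.77.

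The first comparison asked what separated the 2 states of the NOD lines, the EpiSC-like state and the ES state. Most genes that mark naive ES cells were lower in the EpiSC-like lines. Dppa5a, an ES cell RNA-binding protein gene, fell by 9.58 ± 0.17 (log2 ± SE, 6 arrays against 3, adjusted p = 4.66e-11). Tdh, the threonine dehydrogenase of ES cells, fell by 9.23 ± 0.36 (adjusted p = 4.56e-08). Nr0b1, a naive-state nuclear receptor, was at least 207-fold lower (adjusted p = 2.66e-06) and Dppa3, a maternal and germ line factor, at least 61.3-fold lower (adjusted p = 1.66e-05). Zfp42 (Rex1) and the orphan receptor gene Esrrb, each well above background on 1 of the 6 EpiSC-like arrays, stood at -9.82 ± 0.74 and -9.31 ± 0.77. The core factor Pou5f1 (Oct4) fell by 6.00 ± 0.57 (adjusted p = 1.1e-05), Nanog by 5.20 ± 0.73 and Sox2 by 2.07 ± 0.50 (adjusted p = 0.00594). Fgf5, a marker of the primed epiblast, rose by 2.40 ± 0.28 (adjusted p = 4.59e-05) as the mean of 2 unlike lines. The iPS line minus the ES line stood at -3.26 for Fgf5, and slide 4, with the ES line alone, gave a rise of 4.13. Cdh2 (N-cadherin) rose by 3.41 ± 0.53, although the mean over all probes put Cdh2 at 0.71 (adjusted p = 0.41).

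Of the 18 naive ES markers, 16 fell and 0 rose by limma, or 17 and 0 adjusted over the list alone (median log2 -4.67, camera adjusted p = 3.62e-07, adjusted p = 0.365 with an estimated correlation). Klf4, a shared naive and reprogramming factor, did not pass at -1.44 ± 0.59 (adjusted p = 0.0744), nor did Klf2 at 0.58 ± 0.32, whose mean over all its probes fell by 1.77. All 10 tested genes of the pluripotency core fell, also adjusted over the list alone (median -3.08, camera adjusted p = 2.17e-05, adjusted p = 0.419 with an estimated correlation). Among them were Lin28a, which binds let-7 precursors (fell by 2.46 ± 0.18), and the Nodal co-receptor gene Tdgf1 (fell by 4.13 ± 0.48). Of the 7 reprogramming factors 5 fell and 0 rose (6 and 0 adjusted over the list alone, median -2.46, camera adjusted p = 0.00681, adjusted p = 0.458 with an estimated correlation), Mycn by 3.05 ± 0.23. The primed epiblast markers split, with 5 up and 4 down of 14 (6 and 4 adjusted over the list alone, median 0.06, camera adjusted p = 0.344). Their median was 1.24 within slide 4 and 1.02 with the slide as a block, and without the 2 arrays of doubtful label it was 0.78, with 7 up and 4 down. Otx2, an anterior epiblast regulator, rose by 1.58 ± 0.44 and Sox11 by 2.23 ± 0.24. Nodal, which keeps the epiblast primed, fell by 4.11 ± 0.32 and the DNA methyltransferase Dnmt3b by 2.74 ± 0.26.

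Some neuroectoderm and mesendoderm genes were higher in the NOD EpiSC-like lines, while the trophectoderm list was not called. Neuroectoderm genes rose in 7 of 12 cases and fell in 0 (median 1.56, or 1.21 with genes at their bound, camera adjusted p = 0.000929, adjusted p = 0.365 with an estimated correlation). Zic1, an early neural regulator, rose by 5.31 ± 0.41 and the neuronal Map2 by 3.90 ± 0.40. Mesendoderm genes rose in 7 of 15 cases and fell in 1 (8 and 1 adjusted over the list alone, median 0.99, camera adjusted p = 0.00439, adjusted p = 0.458 with an estimated correlation). Foxa2, of endoderm and node, rose by 5.30 ± 0.37, and the Nodal and WNT antagonist Cer1 was at least 9.85-fold higher. Among the largest rises were the glial Fabp7 (7.92 ± 0.37, adjusted p = 1.46e-07), Gpm6b (7.49 ± 0.36) and the secretory granule gene Chgb (7.52 ± 0.31). Mlc1, an astrocyte membrane gene, was at least 176-fold higher, the neural adhesion gene Chl1 at least 92.5-fold and the gastric Gkn2 at least 105-fold (adjusted p = 2.42e-07).

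Markers of fibroblasts, which serve as feeder cells for such lines, moved with these groups. Of 20 fibroblast genes 15 rose and 0 fell, also adjusted over the list alone (median 2.22, camera adjusted p = 1.89e-07, adjusted p = 0.495 with an estimated correlation). The matrix proteoglycans Lum and Dcn rose by 5.92 ± 0.55 and 5.61 ± 0.61, Col1a2 by 2.33 ± 0.57 and Col1a1 by 1.91 ± 0.61 (adjusted p = 0.0267). Postn (1.13 ± 0.52, adjusted p = 0.114) and the smooth muscle actin Acta2 (1.32 ± 0.79) did not pass. Mesenchymal transition factors rose in 8 of 10 cases and fell in 0 (9 and 1 adjusted over the list alone, median 2.63, camera adjusted p = 0.000146, adjusted p = 0.365 with an estimated correlation), Zeb2 by 3.33 ± 0.67. The epithelial cadherin Cdh1 fell by 2.92 ± 0.50. Epithelial genes as a list went both ways, with 1 up and 6 down of 13, a median of 0.06 and a mean of -0.54 (camera adjusted p = 0.668). Without the 2 arrays of doubtful label 5 rose and 5 fell, with a median of 0.08.

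Antigen presentation genes rose in 12 of 15 cases and fell in 0 (median 2.64, camera adjusted p = 6.98e-06, adjusted p = 0.411 with an estimated correlation). B2m, the shared light chain of class I molecules, rose by 4.53 ± 0.39 and H2-K1 by 3.86 ± 0.41. Imprinted genes, expressed from 1 parental allele, rose in 10 of 21 cases and fell in 2 (10 and 3 adjusted over the list alone, median 1.44, camera adjusted p = 0.0032, adjusted p = 0.568 with an estimated correlation). Their call was lost with normexp (adjusted p = 0.42), and their median was 2.22 without the doubtful arrays. Dlk1 rose by 6.37 ± 0.78, H19 by 5.82 ± 0.46 and Igf2 by 4.28 ± 0.45. Germ cell genes fell in 13 of 16 cases and rose in 1 (median -3.94, or -3.13 with genes at their bound, camera adjusted p = 2.31e-05, adjusted p = 0.365 with an estimated correlation), which normexp reduced to a median of -0.06 (adjusted p = 0.13). Tex19.1, a transposon defence gene, fell by 8.80 ± 0.15 and the germ line helicase Ddx4 was at least 37.9-fold lower. DNA methylation enzymes fell in 6 of 8 cases and rose in 1 (median -2.34, camera adjusted p = 0.00424, adjusted p = 0.226 with an estimated correlation), Dnmt3l at -7.97 ± 0.28 and the maintenance factor Uhrf1 at -3.47 ± 0.18. Xist, the RNA that silences an X chromosome, was at least 9.87-fold higher (adjusted p = 8.2e-05), and its antisense partner Tsix fell by 3.71 ± 0.43. Of the 4 Y-linked genes 0 passed by limma (median 1.00, camera adjusted p = 0.593, Eif2s3y at 1.71 ± 1.11 with adjusted p = 0.26 and Ddx3y at 1.32 ± 1.09).

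The remaining lists were not called. The counts up and down were 1 and 3 of 10 for trophectoderm (median -1.43, camera adjusted p = 0.431), 2 and 4 of 10 for Nodal-SMAD2/3 targets (median -0.71) and 3 and 6 of 12 for FGF-ERK feedback genes (median -0.80). They were 3 and 4 of 12 for LIF-STAT3 targets (median -0.55, mean -0.96, camera upward) and 5 and 2 of 12 for WNT targets (median -0.27, mean 0.12, camera upward). Within slide 4 the Nodal median was 0.54, the WNT median 1.2 (0.38 with the slide as a block), the FGF-ERK median -0.04, the trophectoderm median -0.49 and the LIF-STAT3 median -1.16. The 2-cell-stage genes gave 0 and 3 of 6 (median -2.57, or -0.93 within slide 4 and -0.61 with the block), glycolysis 3 and 7 of 19 (median -0.06, camera upward), cytochrome c oxidase 1 and 6 of 13 (median -0.56) and p53 targets 2 and 3 of 10 (median 0.02, mean -0.21).

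In all, 8966 of 23191 genes changed between the NOD states, 3870 higher and 5096 lower in the EpiSC-like lines. With the array labelled NOD ES replicate 1 and that labelled EpiSC iPS replicate 2 left out, 11983 changed. Without them Klf4 (fell by 2.40) and Postn (1.73) passed, as did Eif2s3y (3.48), Ddx3y (3.03) and Acta2 (2.05), and 17 naive markers and 10 core genes fell while 20 fibroblast genes rose. Slide 4 held 1 EpiSC-like and 2 ES arrays, and within it 96.2% of the called genes kept their direction, with Pou5f1 at -4.69, Dppa5a at -9.78 and Fgf5 at 4.13. Here and below, shares of called genes that kept their direction within a slide or with the block rest on arrays that made the calls. They are no independent test. Median differences within that slide were -5.75 for naive markers, -3.28 for the pluripotency core, 2.80 for fibroblast genes, 2.04 for antigen presentation and 2.25 for neuroectoderm. With the slide as a block the same medians were -5.85, -3.34, 2.31, 2.91 and 1.65, and 6138 genes changed. Within the slide and with the block, germ cell medians were -3.10 and -2.98, imprinted medians 2.53 and 2.89, mesendoderm medians 2.31 and 1.33 and DNA methylation medians -2.40 and -2.65. That block kept the direction of 98.5% of the called genes and ended the calls of Sox2 (-2.62 ± 1.01), Cdh2 (3.73 ± 1.14), Dcn (5.52 ± 1.59), Col1a1 (2.03 ± 1.31), Col1a2 (2.78 ± 1.24), Cdh1 (-3.30 ± 1.00) and Zeb2 (3.86 ± 1.47) as their SEs widened, while Otx2 stood at 1.04 ± 0.79. Normexp ended those of Col1a1, Col1a2 and Tsix (-0.41).

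**Figure D2:**
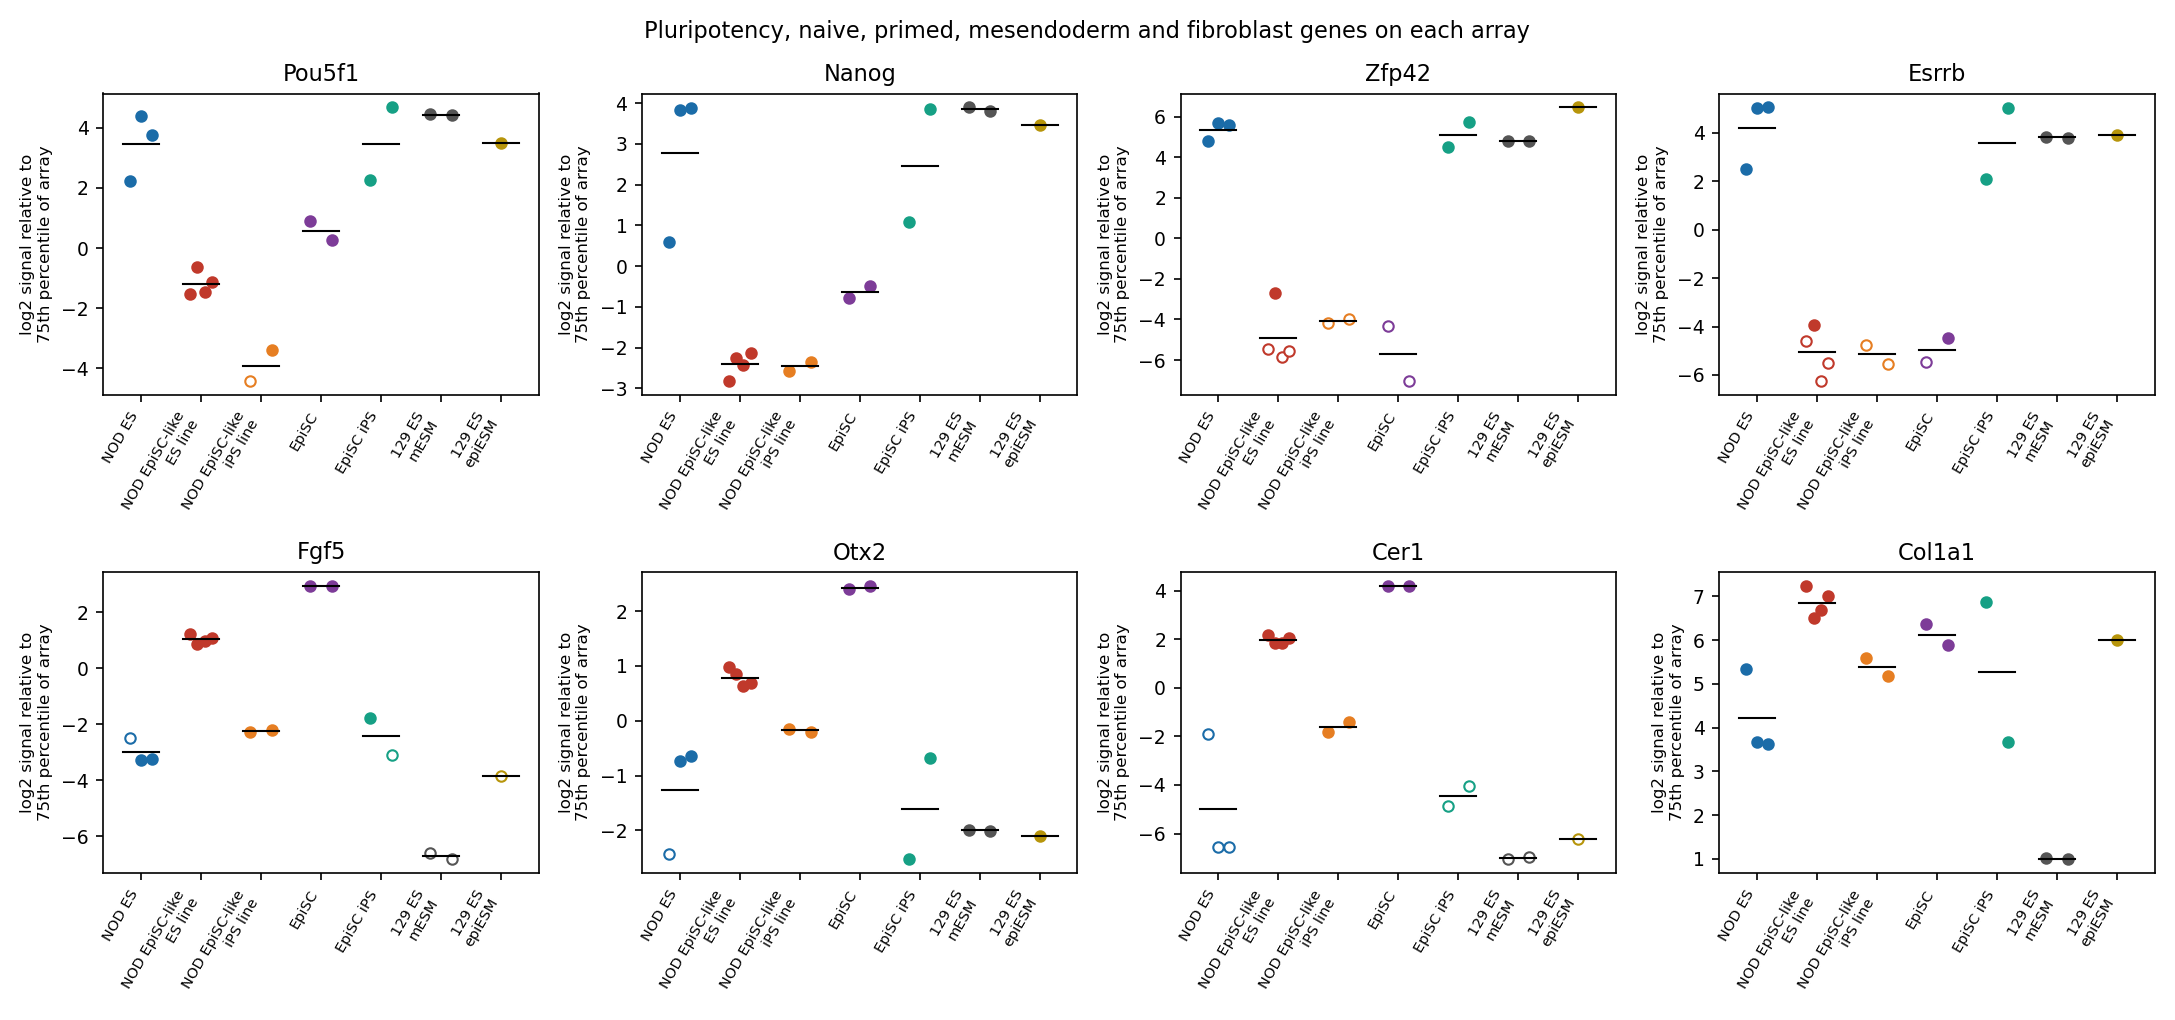
Scaled log2 signal of marker genes on each of the 16 arrays, with bars at the group means, filled points well above background and open points not. Pou5f1 and the naive markers were lowest in the NOD EpiSC-like lines and EpiSC. Col1a1 is the fibroblast gene shown. Fibroblast list means were high in those groups, from 2.95 to 4.15. They were also high on the array labelled EpiSC iPS replicate 1 (3.45) and on epiESM (2.63), where naive markers were high.

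The same question was asked of the non-NOD lines, with EpiSC set against 129 ES cells labelled mESM (2 arrays each). Naive markers again separated the states. Tdh fell by 8.25 ± 0.50 (adjusted p = 1.72e-06) and Esrrb fell by 8.78 ± 1.07. Zfp42 was at least 538-fold lower and Dppa4 at least 211-fold lower (adjusted p = 4.7e-05). Fgf5 was at least 236-fold higher (adjusted p = 1.32e-07), Otx2 rose by 4.43 ± 0.61 and Cdh2 by 6.20 ± 0.74. Pou5f1 fell by 3.86 ± 0.79 (adjusted p = 0.00475), Nanog fell by 4.49 ± 1.02 and Nodal fell by 1.84 ± 0.45, and Dnmt3b did not pass at 0.41 ± 0.36 (adjusted p = 0.424). Nor did Sox2 at -1.44 ± 0.69, Klf2 at -0.94 ± 0.44 or Klf4 at -0.21 ± 0.81.

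Of the 18 naive markers 15 fell and 0 rose (median -4.64, or -4.09 with genes at their bound, camera adjusted p = 6.59e-09, adjusted p = 0.365 with an estimated correlation). Core genes fell in 5 of 10 cases (median -1.36, camera adjusted p = 0.01, adjusted p = 0.739 with an estimated correlation). Primed markers rose in 6 of 14 cases and fell in 1 (7 and 1 adjusted over the list alone, median 1.1, camera adjusted p = 0.000144, adjusted p = 0.226 with an estimated correlation). Mesendoderm genes rose in 9 of 15 cases and fell in 0 (10 and 0 adjusted over the list alone, median 2.55, camera adjusted p = 1.99e-06, adjusted p = 0.302 with an estimated correlation). The organizer gene Gsc rose by 5.97 ± 0.44, Brachyury (T) by 5.82 ± 0.41 and Foxa2 by 7.45 ± 0.51, and Cer1 was at least 566-fold higher. Neuroectoderm genes rose in 8 of 12 cases (8 up and 1 down adjusted over the list alone, median 2.66, camera adjusted p = 0.000236, adjusted p = 0.365 with an estimated correlation), Zic1 by 5.90 ± 0.57. WNT targets rose in 6 of 12 cases and fell in 0 (7 and 2 adjusted over the list alone, median 1.94, camera adjusted p = 0.0027, adjusted p = 0.365 with an estimated correlation). Sp5 rose by 6.28 ± 0.78, and the WNT receptor partner Lgr5 was at least 32.2-fold higher. The immediate early gene Egr1, a readout of ERK signalling, rose by 6.69 ± 0.29 and the ERK phosphatase Dusp4 by 4.37 ± 0.48, while their list of FGF-ERK feedback genes was not called, with 5 up and 2 down of 12 (6 and 2 adjusted over the list alone, median 0.90, camera adjusted p = 0.051).

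Fibroblast genes rose in 17 of 20 cases, or 20 adjusted over the list alone (median 4.32, camera adjusted p = 4.88e-13, adjusted p = 0.365 with an estimated correlation). Postn was at least 227-fold higher, Dcn rose by 7.52 ± 0.85, Col3a1 by 7.03 ± 0.62 and Col1a1 by 5.12 ± 0.84. The mESM arrays had the lowest fibroblast signal of all arrays, with a list mean of -1.42 and -1.43 (log2), against 3.03 and 2.95 in EpiSC. Mesenchymal transition factors rose in 8 of 10 cases (9 up and 0 down adjusted over the list alone, median 2.64, camera adjusted p = 8.77e-06, adjusted p = 0.365 with an estimated correlation). Imprinted genes rose in 11 of 21 cases and fell in 2 (12 up and 2 down adjusted over the list alone, median 1.90, camera adjusted p = 1.57e-05, adjusted p = 0.387 with an estimated correlation), the maternally silenced Mest by 9.36 ± 0.47, H19 by 6.31 ± 0.63 and Nnat by 7.33 ± 0.68. Germ cell genes fell in 11 of 16 cases and rose in 1 (1 up and 14 down adjusted over the list alone, median -4.97, or -3.51 with genes at their bound, camera adjusted p = 2.44e-06, adjusted p = 0.365 with an estimated correlation), and Dnmt3l fell by 7.79 ± 0.39. Of 4 Y-linked genes 3 rose (median 5.14, or 3.97 with genes at their bound, camera adjusted p = 0.00556, adjusted p = 0.412 with an estimated correlation). Eif2s3y was at least 107-fold higher and Ddx3y at least 67.9-fold higher, neither being above background in the mESM arrays. Xist did not pass at 1.34 ± 0.75, and Tsix was at least 7.97-fold lower.

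A total of 5703 genes changed, 2769 higher and 2934 lower in EpiSC (931 and 587 after normexp, which ended the calls of Nodal and Tsix), and 10620 changed without the 2 arrays of doubtful label. The count fell to 3220 and 3050 without either EpiSC array and to 2804 without either mESM array. No slide held both groups. With the slide as a block the medians were -4.80 for naive markers and 4.28 for fibroblast genes, 2026 genes changed and 100% of the called genes kept their direction. Pou5f1 (-3.48 ± 1.195, adjusted p = 0.141), Nanog (-4.01 ± 1.29), Nodal (-1.79 ± 0.60), Dcn (7.40 ± 1.81), Col1a1 (5.16 ± 1.48) and Ddx3y lost their calls to wider SEs.

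The NOD and non-NOD differences were then set side by side, as both contrast an EpiSC-type state with ES cells and share no array. Across 23191 genes their Pearson correlation was 0.633 and their Spearman correlation 0.496, with 70.0% of genes on the same side of 0, where genes are not independent replicates. Both called 1827 genes higher, against 462 expected for independent lists, and 1830 lower, against 645. They called 113 and 121 genes in opposite directions, against 490 and 608 expected.

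A test of the difference between the differences called 2903 genes, 1159 higher and 1744 lower in the NOD difference, or 8190 without the arrays of doubtful label. The NOD difference minus the non-NOD difference was -3.16 ± 0.45 for Dnmt3b, -6.69 ± 0.35 for Egr1 (adjusted p = 9.03e-06) and -4.81 ± 0.51 for T. It was 3.00 ± 0.70 for H2-K1 (adjusted p = 0.0175). The NOD difference itself, the mean of both lines, was 0.004 for Egr1 and 1.02 for T. The EpiSC-like iPS line minus the ES line stood at -5.55 for Egr1, -3.71 for T and -3.25 for Dnmt3b, so the lines were unlike here. Egr1 also stood 4.16 higher in NOD ES than in mESM. Fgf5 was called lower (adjusted p = 2.98e-05) and Gkn2 higher in the NOD difference, with no measured size because some groups were not above background. Primed markers were lower by this test in 6 of 14 cases (8 adjusted over the list alone, median -1.85, camera adjusted p = 6.88e-05, adjusted p = 0.226 with an estimated correlation). WNT targets were lower in 6 of 12 cases (median -1.46, camera adjusted p = 0.00439, adjusted p = 0.365 with an estimated correlation), and antigen presentation genes higher in 5 of 15 (7 up and 0 down adjusted over the list alone, median 1.88, camera adjusted p = 0.000397, adjusted p = 0.495 with an estimated correlation). The fibroblast list moved with them, lower in 3 of 20 cases (5 adjusted over the list alone, median -1.92, camera adjusted p = 0.00441, adjusted p = 0.838 with an estimated correlation). Camera also called lower the mesendoderm (median -1.84, adjusted p = 0.0052, or 0.462 with an estimated correlation), Nodal-SMAD2/3 (-1.84, 0.00715 or 0.226), FGF-ERK feedback (-0.51, 0.0052 or 0.365), core (-1.38, 0.0273 or 0.753), reprogramming (-1.23, 0.0156 or 0.495) and Y-linked lists (-4.15, 0.0205 or 0.462). Without the doubtful arrays the FGF-ERK median was -1.08, and with the slide as a block the mesendoderm call ended (adjusted p = 0.0547). After normexp only 30 genes passed, 7 of them higher. Of the calls, 51.8% were higher in the value table, against 39.9% here. Taking the slide as a block, 277 genes passed, while 99.966% of the 2903 kept their direction. The count was 4954 without the array labelled NOD ES replicate 1, 1304 and 1328 without either EpiSC array and 1029 and 1015 without either mESM array.

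**Figure D3:**
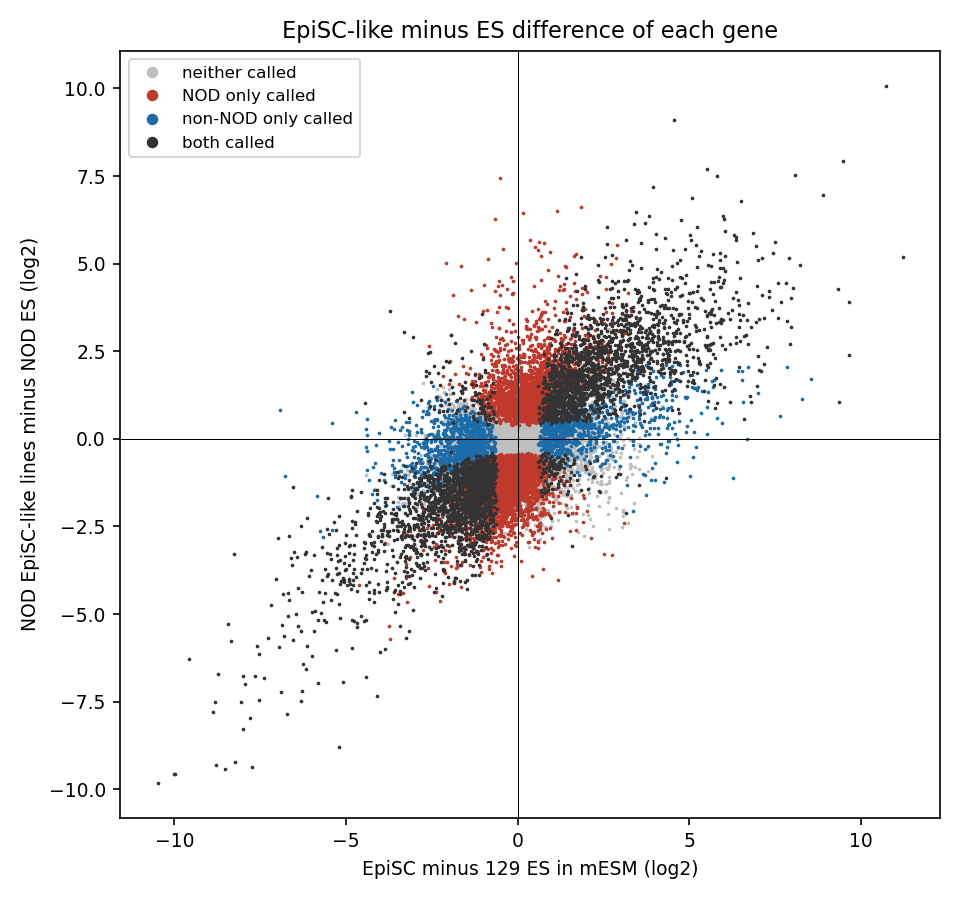
Each point is 1 of 23191 genes, with the EpiSC minus 129 mESM difference on the horizontal axis and the NOD EpiSC-like minus NOD ES difference on the vertical axis, both in log2. The Pearson correlation across genes was 0.633.

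The iPS lines named after EpiSC were compared with EpiSC, 2 arrays each, to ask how far they had left the primed state. Naive markers were high in the iPS lines. Dppa5a rose by 10.16 ± 0.23 (adjusted p = 1.81e-09), Tdh by 9.46 ± 0.50 and Esrrb by 8.55 ± 1.07. Zfp42 was at least 664-fold higher (adjusted p = 4.63e-05) and Dppa3 at least 92.6-fold higher. Pou5f1 rose by 2.89 ± 0.79 (adjusted p = 0.0233). Nanog (3.10 ± 1.02, adjusted p = 0.051) and Sox2 (0.31 ± 0.69) did not pass. Fgf5 fell by 5.37 ± 0.39, Otx2 by 4.04 ± 0.61, Cdh2 by 4.46 ± 0.74 (-1.17 over all its probes, adjusted p = 0.364) and Foxa2 by 5.99 ± 0.51. All these directions rest partly on the array labelled EpiSC iPS replicate 2, without which, and without the array labelled NOD ES replicate 1, Sox2 fell by 0.91 (adjusted p = 0.0049) and Nanog rose by 1.72.

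Of 18 naive markers 13 rose and 0 fell (15 and 0 adjusted over the list alone, median 5.20, camera adjusted p = 1.68e-08, adjusted p = 0.365 with an estimated correlation). Primed markers fell in 7 of 14 cases and rose in 1 (1 up and 8 down adjusted over the list alone, median -1.54, camera adjusted p = 1.16e-05, adjusted p = 0.226 with an estimated correlation). Mesendoderm genes fell in 8 of 15 cases (0 up and 9 down adjusted over the list alone, median -1.57, or -1.54 with genes at their bound, camera adjusted p = 1.87e-06, adjusted p = 0.302 with an estimated correlation). Neuroectoderm genes fell in 6 of 12 cases (0 up and 7 down adjusted over the list alone, median -2.69, or -1.69 with genes at their bound, camera adjusted p = 1.16e-05, adjusted p = 0.302 with an estimated correlation), and Fabp7 was at least 110-fold lower. Germ cell genes rose in 11 of 16 cases and fell in 1 (12 up and 1 down adjusted over the list alone, median 4.52, or 3.24 with genes at their bound, camera adjusted p = 8.5e-06, adjusted p = 0.365 with an estimated correlation), and Tex19.1 rose by 6.74 ± 0.21. Imprinted genes fell in 10 of 21 cases and rose in 1 (median -1.81, camera adjusted p = 0.000397, adjusted p = 0.458 with an estimated correlation), and Nnat was at least 40.3-fold lower. Without the 2 doubtful arrays the imprinted median was -0.28, with 2 up and 10 down. The 2-cell-stage gene Zscan4c rose by 4.96 ± 0.96 and Tcstv1 by 5.93 ± 1.53 (adjusted p = 0.0176), the latter standing at -0.09 with the slide as a block.

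Several weaker list calls in this comparison turned on the doubtful arrays, the slide or the scaling. Fibroblast genes fell in 3 of 20 cases (median -0.95, camera adjusted p = 0.0023, adjusted p = 0.785 with an estimated correlation), Lum by 3.65 ± 0.76, Dcn by 2.98 ± 0.85 and the matrix protease Mmp2 by 2.26 ± 0.44, while Col1a1 stood at -0.86 ± 0.84. Without the 2 doubtful arrays 7 fibroblast genes rose, 3 fell and the median was 0.28. The FGF-ERK feedback genes (2 up and 6 down adjusted over the list alone, 5 of 12 down, camera adjusted p = 0.00982, adjusted p = 0.365 with an estimated correlation) and WNT targets (2 up and 6 down adjusted over the list alone, 5 of 12 down, camera adjusted p = 0.00242, adjusted p = 0.365 with an estimated correlation) lost their calls with the slide as a block (adjusted p = 0.766 and 0.138), while 9 FGF-ERK genes fell and 2 rose without the doubtful arrays. Antigen presentation genes (6 of 15 down, camera adjusted p = 0.0109, adjusted p = 0.747 with an estimated correlation) and cytochrome c oxidase genes (5 up and 1 down adjusted over the list alone, 4 of 13 up, camera adjusted p = 0.0302, adjusted p = 0.753 with an estimated correlation) lost theirs with quantile normalization and without the doubtful arrays (adjusted p = 0.291 and 0.0835). Mesenchymal factors fell in 4 of 10 cases (median -1.24, camera adjusted p = 0.00247, adjusted p = 0.458 with an estimated correlation), with a median of -0.08 without the doubtful arrays.

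The iPS lines and EpiSC differed in 4896 genes, 2815 higher and 2081 lower in EpiSC iPS. After quantile normalization the split was 2000 higher and 2714 lower, and 43.6% were higher in the value table. Normexp left 748 genes and ended the calls of Pou5f1 (2.72, adjusted p = 0.099), Lum, Dcn, Mmp2, Tcstv1 and Zscan4c. Without both doubtful arrays 9735 genes changed, without the array labelled NOD ES replicate 1 alone 7419, and without either EpiSC array 2739 and 2455. No slide held both groups, and with the slide as a block, which ties EpiSC iPS to the other groups only through the array labelled NOD ES replicate 1, 5370 genes changed, the naive median was 5.82 and Nanog (6.00) gained a call. Pou5f1 (3.87 ± 1.51, adjusted p = 0.113), Cdh2 (-5.75 ± 1.64), Lum (-4.05 ± 1.97), Dcn (-3.05 ± 2.29) and Mmp2 (-2.92 ± 0.99) lost their calls to wider SEs, and Otx2 (-2.35 ± 1.13), Dppa3 and Zscan4c (2.61 ± 1.86) to smaller differences too.

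To ask how the EpiSC-like lines resemble the cells they are named after, the NOD EpiSC-like lines (6 arrays) were compared with EpiSC (2 arrays), which also differ in strain. Of 18 naive markers 0 passed by limma in either direction (median 0.30, or 0.00 with genes at their bound, camera adjusted p = 0.894), and Zfp42 had no measurable fold. Without the 2 arrays of doubtful label 3 rose and 2 fell at the same median, since only the pooled spread changed. Genes of the primed state were lower in the NOD lines, given as the mean of both lines. Fgf5 fell by 3.54 ± 0.32 (adjusted p = 7.91e-05), Dnmt3b by 3.62 ± 0.30, Otx2 by 2.13 ± 0.51 and Nodal by 2.18 ± 0.37. Pou5f1 fell by 3.13 ± 0.66 (adjusted p = 0.00864) and Lin28a by 2.16 ± 0.21, while Nanog (-1.80 ± 0.84, adjusted p = 0.168) and Sox2 (-1.20 ± 0.57) did not pass. After normexp Pou5f1 stood at -0.95 (adjusted p = 0.245). The lysozyme genes Lyz1 and Lyz2, usual in macrophages and Paneth cells, rose by 9.67 ± 1.08 and 9.34 ± 1.04, and Gkn2 was at least 233-fold higher (adjusted p = 2.13e-06).

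Primed markers fell in 9 of 14 cases and rose in 0 (median -1.69, camera adjusted p = 1.89e-07, adjusted p = 0.156 with an estimated correlation). Core genes fell in 5 of 10 cases (median -1.51, camera adjusted p = 5.65e-05, adjusted p = 0.454 with an estimated correlation) and reprogramming factors in 3 of 7 (median -1.80, camera adjusted p = 0.000387, adjusted p = 0.365 with an estimated correlation). Nodal-SMAD2/3 targets fell in 6 of 10 cases (7 adjusted over the list alone, median -1.82, camera adjusted p = 1.08e-05, adjusted p = 0.128 with an estimated correlation), Lefty1, a Nodal antagonist, by 4.29 ± 0.75 and Lefty2 by 2.78 ± 0.29. WNT targets fell in 8 of 12 cases (1 up and 8 down adjusted over the list alone, median -1.77, camera adjusted p = 0.000144, adjusted p = 0.302 with an estimated correlation), T standing at -3.77 ± 0.34 and Sp5 at -3.58 ± 0.65. FGF-ERK feedback genes fell in 5 of 12 cases and rose in 1 (median -0.85, camera adjusted p = 0.00123, adjusted p = 0.302 with an estimated correlation), Egr1 by 2.53 ± 0.24 and the ERK phosphatase Dusp6 by 2.09 ± 0.39. For Egr1 this came from the iPS line, with group means of 0.24 there, 5.80 in the ES line and 5.55 in EpiSC (log2). Mesendoderm genes fell in 6 of 15 cases and rose in 1 (2 up and 7 down adjusted over the list alone, median -0.46, camera adjusted p = 0.00504, adjusted p = 0.462 with an estimated correlation), Cer1 by 4.02 ± 0.98. DNA methylation enzymes fell in 4 of 8 cases (median -0.66, camera adjusted p = 0.016, or 0.0597 without the doubtful arrays, adjusted p = 0.29 with an estimated correlation).

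Antigen presentation genes rose in 7 of 15 cases and fell in 1 (11 and 1 adjusted over the list alone, median 1.23, camera adjusted p = 0.0032, adjusted p = 0.652 with an estimated correlation), a call that normexp ended (adjusted p = 0.76). H2-K1 rose by 1.68 ± 0.47 (0.66 over all its probes, adjusted p = 0.106), the peptide transporter Tap1 by 1.63 ± 0.44 and the adhesion gene Icam1 by 2.58 ± 0.17. Xist rose by 3.17 ± 0.63 (adjusted p = 0.00626). Of 20 fibroblast genes 0 passed by limma in either direction (median 0.60, camera adjusted p = 0.33), and Col1a1 stood at -0.01 ± 0.70. Without the doubtful arrays 11 rose and 2 fell at the same median, again through the pooled spread alone.

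The comparison called 3725 genes, 1824 higher and 1901 lower in the NOD lines, or 9561 without the doubtful arrays and 775 after normexp, which ended the calls of Nodal (-1.51, adjusted p = 0.0775), Sp5 (-2.04), H2-K1 (0.40), Tap1 (1.41) and Icam1 (1.33). The count was 1087 and 1017 without either EpiSC array, 2472 without EpiSC-like iPS replicate 2 and 6344 without the array labelled NOD ES replicate 1. On slide 1, which held EpiSC and both NOD lines, and slide 3, which held EpiSC and the ES line alone, 100% and 95.9% of called genes kept their direction. The same arrays helped to make these calls, so such shares were to be high. The primed median was -1.65 on slide 1, -1.60 on slide 3 and -1.70 with the slide as a block. The medians for Nodal-SMAD2/3 targets were -2.02, -1.70 and -1.98, those for WNT targets -1.62, -0.67 and -1.77, and those for FGF-ERK feedback genes -0.86, -0.07 and -0.90. Egr1 stood at -2.16 on slide 1 and 0.08 on slide 3. On slide 3 other falls were smaller too, with Fgf5 at -1.96, T at -2.00, Sp5 at -1.60, Lefty1 at -1.92, Cer1 at -2.34, Dnmt3b at -2.17, Dusp6 at -1.11 and Pou5f1 at -1.74. The block, with which 2700 genes passed, ended the calls of Otx2 (-2.14 ± 0.55), Dusp6 (-1.98 ± 0.55) and H2-K1 (1.79 ± 0.54).

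The NOD EpiSC-like iPS line 6 (2 arrays) was compared with EpiSC-like ES line 1 (4 arrays). Each origin had 1 line, so line and origin cannot be told apart. Readouts of FGF-ERK signalling were lower in the iPS line, although after normexp only Egr1 and Egr2 of those named stayed called. WNT readouts were lower before but not after normexp. Egr1 fell by 5.55 ± 0.25 (adjusted p = 7.26e-07) and Egr2 by 6.42 ± 0.23, and Egr3 was at least 20.1-fold lower. The WNT feedback gene Axin2 fell by 3.88 ± 0.44 and Sp5 fell by 4.01 ± 0.67. Pou5f1 fell by 2.73 ± 0.69 (adjusted p = 0.0141), Sox2 by 2.22 ± 0.59 and Myc by 1.72 ± 0.26, while Nanog did not pass at -0.05 ± 0.88. After normexp Egr1 (-5.03), Egr2 (-2.53) and Col3a1 alone of the genes named here passed, with Pou5f1 at 0.38, Axin2 at -0.20 (adjusted p = 0.563), Sp5 at -0.80, Egr3 at -0.44, Dnmt3b at -0.62 and Krt19 at 0.82. The muscle gene Trim55 rose by 7.46 ± 1.14, Cdcp1 by 7.04 ± 1.24 and the LIF receptor gene Lifr by 6.53 ± 1.19 (adjusted p = 0.0025).

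FGF-ERK feedback genes fell in 8 of 12 cases (9 adjusted over the list alone, median -1.97, camera adjusted p = 3.64e-06, adjusted p = 0.226 with an estimated correlation), Spry2 by 2.35 ± 0.43 (-0.75 over all its probes, adjusted p = 0.138). WNT targets fell in 8 of 12 cases (9 adjusted over the list alone, median -1.80, turning to 0.22 with normexp, camera adjusted p = 5.11e-05, adjusted p = 0.302 with an estimated correlation). Nodal-SMAD2/3 targets fell in 5 of 10 cases (median -1.105, or -0.55 with genes at their bound, camera adjusted p = 0.00473, adjusted p = 0.226 with an estimated correlation), Lefty1 by 4.40 ± 0.79. Primed markers fell in 4 of 14 cases (median -1.03, or -0.94 with genes at their bound, camera adjusted p = 0.00422, adjusted p = 0.331 with an estimated correlation), Fgf5 by 3.26 ± 0.34 and Dnmt3b by 3.25 ± 0.31. Reprogramming factors fell in 4 of 7 cases (median -1.103, turning to 0.12 with normexp, camera adjusted p = 0.00747, adjusted p = 0.458 with an estimated correlation).

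Glycolysis genes rose in 12 of 19 cases and fell in 0 (median 1.00, camera adjusted p = 0.000144, adjusted p = 0.458 with an estimated correlation), a direction that normexp reversed (median -0.71). The lactate transporter Slc16a3 rose by 2.33 ± 0.27, Gpi1 by 2.08 ± 0.30 and Tpi1 by 1.91 ± 0.21. Epithelial genes rose in 8 of 13 cases and fell in 1 (9 up and 1 down adjusted over the list alone, median 1.21, camera adjusted p = 0.00649, adjusted p = 0.419 with an estimated correlation, not called with normexp), Krt19 by 2.96 ± 0.20 and the tight junction gene Cldn7 by 1.96 ± 0.20. Antigen presentation genes rose in 4 of 15 cases (median 1.09, turning to -0.21 with normexp, camera adjusted p = 0.0267, adjusted p = 0.753 with an estimated correlation). Xist rose by 2.18 ± 0.65 (adjusted p = 0.0311), and Tsix was at least 2.36-fold higher. Fibroblast genes fell in 5 of 20 cases, or 2 adjusted over the list alone (median -0.90, camera adjusted p = 0.00736, adjusted p = 0.838 with an estimated correlation), Col3a1 by 2.60 ± 0.53. The fibroblast marker Thy1 stood at 1.39 ± 0.82.

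In total 5958 genes changed, 3278 higher and 2680 lower in the iPS line, or 2713 and 3365 after quantile normalization and 1 and 59 after normexp. Without the doubtful arrays 11729 changed, and without EpiSC-like iPS replicate 2, 2485. Slide 1 held 1 array of each line, with Egr1 at -5.79 and medians of -1.90 for FGF-ERK feedback genes, -2.00 for WNT targets and 0.99 for glycolysis. There 5945 of 5947 called genes kept their direction, although these arrays also helped to make the calls. With the slide as a block these medians were -1.89, -1.95 and 0.97, 2134 genes changed and 100% of the called genes kept their direction. Pou5f1 (-3.07 ± 1.00, adjusted p = 0.113), Sox2 (-2.05 ± 0.96), Myc (-1.75 ± 0.47), Lefty1 (-4.36 ± 1.00), Spry2 (-2.57 ± 0.62), Xist (2.16 ± 0.66) and Col3a1 (-2.75 ± 0.87) lost their calls with differences about as large.

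ES cells of both strains were compared as NOD ES (3 arrays) minus 129 mESM (2 arrays), where culture and strain differ together. Few core and naive genes passed with all arrays, and more did without the 2 of doubtful label. Pou5f1 stood at -0.98 ± 0.72 (adjusted p = 0.434) and Nanog at -1.08 ± 0.93, and 1 of 10 core genes and 1 of 18 naive markers fell. These were Tdgf1 (fell by 2.27 ± 0.60) and Gbx2, a naive homeobox factor (fell by 2.31 ± 0.40, or -1.61 over all its probes with adjusted p = 0.126). Without the array labelled NOD ES replicate 1 and that labelled EpiSC iPS replicate 2, 7 naive markers rose and 1 fell (median 1.01), and 3 core genes rose and 1 fell (median 0.00). The primed marker Fgf5 was at least 3.84-fold higher in NOD ES (adjusted p = 0.000348). Fibroblast genes rose in 9 of 20 cases and fell in 0 (12 and 0 adjusted over the list alone, median 2.48, camera adjusted p = 1.87e-06, adjusted p = 0.568 with an estimated correlation). Postn was at least 69.0-fold higher, Col3a1 rose by 4.92 ± 0.56 and Col1a1 by 3.21 ± 0.77. The imprinted genes Mest and Usp29 rose by 6.61 ± 0.43 and 6.32 ± 0.60, and Egr1 by 4.16 ± 0.26. The X-linked homeobox gene Rhox5 fell by 4.47 ± 0.72. Targets of p53 rose in 4 of 10 cases (5 adjusted over the list alone, median 0.74, camera adjusted p = 0.00243, adjusted p = 0.226 with an estimated correlation), Sesn2 by 2.21 ± 0.26 and Phlda3 by 1.86 ± 0.47. Antigen presentation genes fell in 3 of 15 cases (1 up and 4 down adjusted over the list alone, median -0.70, camera adjusted p = 0.0201, adjusted p = 0.753 with an estimated correlation, not called with quantile normalization). Glycolysis genes fell in 2 of 19 cases (median -0.24, turning to 0.20 with the slide as a block and 0.14 without the doubtful arrays, camera adjusted p = 0.00439, adjusted p = 0.654 with an estimated correlation), the glucose transporter Slc2a1 by 1.56 ± 0.22.

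This comparison called 2068 genes, 1359 higher and 709 lower in NOD ES, and 1032 and 872 after quantile normalization. The share higher was 65.7%, against 40.6% in the value table. After normexp 33 genes passed, and the calls of Tdgf1, Gbx2, Fgf5 (0.82), Postn, Col1a1, Sesn2, Phlda3 and Slc2a1 ended. With the slide as a block 0 genes passed by limma (3537 at an unadjusted p under 0.05), 99.6% of the called genes kept their direction, no slide held both groups, and the block medians were 1.99 for fibroblast genes and 0.85 for p53 targets. Without both doubtful arrays 5995 genes changed. The count was 145 and 162 without either mESM array, 1364 without NOD ES replicate 3 and 3228 without either EpiSC iPS array.

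EpiSC iPS (2 arrays) were also compared with 129 mESM, as non-NOD cells of the ES-like state from another origin. Zfp42 (0.30 ± 1.02) and Pou5f1 (-0.96 ± 0.79) did not differ beyond the spread of the arrays, and only Tdgf1 (fell by 2.80 ± 0.66) of the core and Gbx2 (fell by 2.36 ± 0.44, or -1.27 over all its probes with adjusted p = 0.243) of the naive markers passed. Fibroblast genes rose in 12 of 20 cases (17 adjusted over the list alone, median 3.55, camera adjusted p = 1.84e-10, adjusted p = 0.419 with an estimated correlation). Postn was at least 110-fold higher, and Col1a1 rose by 4.27 ± 0.84 (adjusted p = 0.00988). The array labelled EpiSC iPS replicate 1 had a fibroblast list mean of 3.45 and the array labelled EpiSC iPS replicate 2 one of 0.56. Mesenchymal factors rose in 2 of 10 cases (3 up and 0 down adjusted over the list alone, median 1.52, or 2.77 without the doubtful arrays, camera adjusted p = 0.0032, adjusted p = 0.458 with an estimated correlation), Snai1 by 2.54 ± 0.42. Targets of p53 rose in 5 of 10 cases (6 up and 0 down adjusted over the list alone, median 0.75, camera adjusted p = 0.00243, adjusted p = 0.226 with an estimated correlation), Sesn2 by 2.36 ± 0.28. Glycolysis genes fell in 3 of 19 cases (1 up and 4 down adjusted over the list alone, median -0.36, turning to 0.60 with the slide as a block, camera adjusted p = 0.026, adjusted p = 0.753 with an estimated correlation). Mest rose by 6.65 ± 0.47.

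In this comparison 2462 genes changed, 1567 higher and 895 lower in EpiSC iPS, 1156 and 1114 after quantile normalization, and 3 and 4 after normexp, where Mest alone of the genes named here passed. The share higher was 46.4% in the value table. With the slide as a block 1670 genes changed, the fibroblast median was 1.88, and Postn, Tdgf1 (-2.23 ± 1.18), Fgf5, Col1a1 (3.09 ± 1.99) and Snai1 (2.76 ± 1.03) lost their calls as SEs widened. Without the doubtful arrays 8600 genes changed and Pou5f1 passed (fell by 2.18, adjusted p = 0.00964), as did 7 core genes, all lower. The count was 265 and 255 without either mESM array, 1592 without EpiSC iPS replicate 1, 4641 without the array labelled EpiSC iPS replicate 2 and 5125 without that labelled NOD ES replicate 1.

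Last, the single 129 array labelled epiESM was compared with the 2 labelled mESM, on the assumption that the lone array varied like the other groups. The comparison holds 1 culture on one side and perhaps 1 on the other, its spread comes from the other groups, and without either mESM array the 919 calls fell to 99 and 104, so the values below describe these arrays and not the cultures in general. Pluripotency genes showed no called difference, with 0 of 10 core genes (median -0.19) and 0 of 18 naive markers (median 0.17) passing by limma. Pou5f1 stood at -0.94 ± 0.97 (adjusted p = 0.717), Nanog at -0.40 ± 1.25 and Zfp42 at 1.65 ± 1.25. WNT targets rose in 4 of 12 cases (5 adjusted over the list alone, median 1.76, camera adjusted p = 2.57e-05, adjusted p = 0.29 with an estimated correlation), Sp5 by 7.14 ± 0.95 and Axin2 by 3.59 ± 0.63, with Lgr5 at least 9.25-fold higher. Fibroblast genes rose in 10 of 20 cases (16 adjusted over the list alone, median 3.97, camera adjusted p = 5.98e-15, adjusted p = 0.365 with an estimated correlation). Postn was at least 406-fold higher (adjusted p = 0.000646), and Col3a1 rose by 6.45 ± 0.75. Mesenchymal factors rose in 2 of 10 cases (6 up and 0 down adjusted over the list alone, median 2.33, camera adjusted p = 0.000353, adjusted p = 0.387 with an estimated correlation). Imprinted genes rose in 3 of 21 cases and fell in 1 (5 up and 1 down adjusted over the list alone, median 1.41, camera adjusted p = 0.0212, adjusted p = 0.747 with an estimated correlation, not called with normexp), Usp29 by 8.60 ± 0.80 and Mest by 7.54 ± 0.57. Of 4 Y-linked genes 1 rose (3 adjusted over the list alone, median 4.99, or 3.63 with genes at their bound, camera adjusted p = 0.00149, adjusted p = 0.365 with an estimated correlation), Eif2s3y being at least 187-fold higher (adjusted p = 0.0224). The 2-cell-stage gene Zscan4c rose by 4.84 ± 1.18 (4 up and 0 down adjusted over the list alone, list median 4.25, camera adjusted p = 0.00243, adjusted p = 0.468 with an estimated correlation). The keratin gene Krt2 rose by 10.37 ± 1.34 and Trim55 by 9.66 ± 1.61. Of 10 p53 targets 1 rose (median 0.35, camera adjusted p = 0.0404, adjusted p = 0.365 with an estimated correlation), a call absent after quantile normalization and without the doubtful arrays.

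The epiESM array differed in 919 of 23190 genes, 551 higher and 368 lower. The share higher was 60%, against 49.1% in the value table. After normexp 21 passed and the calls of Lgr5, Eif2s3y and Zscan4c ended. Under the slide block 78 passed, the fibroblast median was 4.09 and the WNT median 1.84, and 100% of the called genes kept their direction. The calls of Sp5 (7.19 ± 1.04), Col3a1 (6.33 ± 1.23), Usp29 (7.86 ± 1.53), Zscan4c (5.53 ± 1.74), Krt2 (7.78 ± 1.85), Trim55 (6.96 ± 1.51), Postn, Lgr5 and Eif2s3y ended there. The count without the doubtful arrays was 5746. Without either mESM array the calls of Axin2, Lgr5, Eif2s3y, Zscan4c and Trim55 ended. The count was 542 without either EpiSC array, 2082 without either EpiSC iPS array, 2571 without the array labelled NOD ES replicate 1, and 543 and 562 without EpiSC-like ES replicates 3 and 4.

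**Figure D4:**
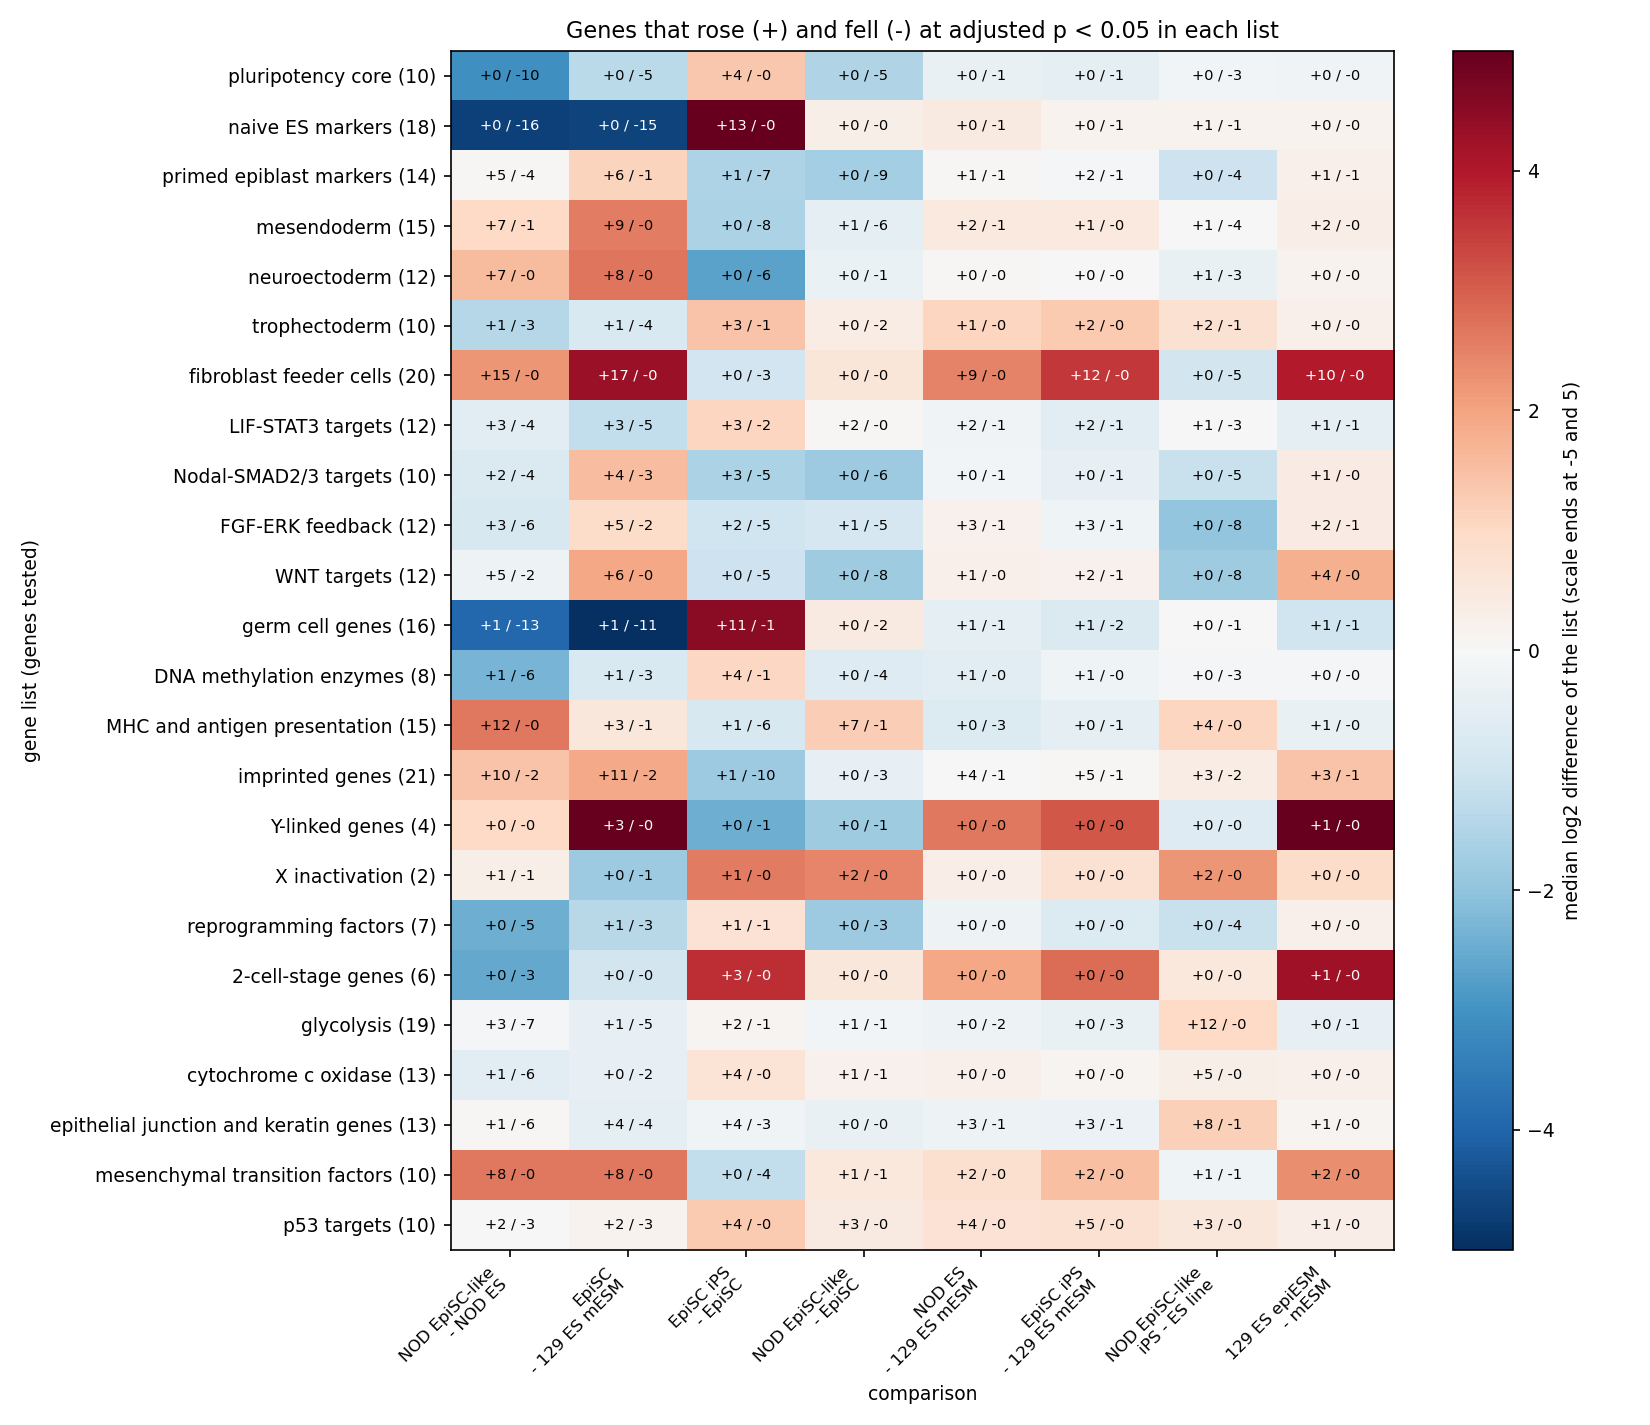
Median log2 difference of each of the 24 gene lists in each comparison, with the counts of genes that rose and fell. Naive markers had medians of -4.67 and -4.64 in the NOD and non-NOD comparisons of EpiSC-type with ES cells.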

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

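The tests of weak signal, of the label and slide of single arrays and of feeder RNA were chosen only after the results were seen.

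Among 108 sets of 4 values in the EpiSC-like ES line, 6 held an array far from the other 3, close to the 1 in 20 that chance gives. These were replicate 1 for the imprinted list mean (1.12, log2), Cdh2 (1.75), Col1a2 (7.45) and Egr2 (3.12), and replicate 2 for Zfp42 (-2.71) and Icam1 (3.20). Replicate 2 had the highest share of spots well above background, 88.5%, and replicate 1 the lowest of this line, 56.8%. The Zfp42 value of replicate 2 was the only one of the 6 EpiSC-like arrays well above background.

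The difference between the EpiSC-type and ES states differed between NOD and non-NOD lines for 27 of 69 named genes tested. For Fgf5, Cer1, Sox9, Lgr5, Eif2s3y, Postn, Mmp3, Mlc1 and Gkn2 some groups were not above background, so their values are fitted to signals near the floor and are no measured fold. Primed and early lineage genes stood lower in the NOD difference, with Fgf5 at -7.26, Otx2 at -2.85, Nodal at -2.27, Dnmt3b at -3.16 and Sall2 at -1.94 (log2). So did T at -4.81, Gsc at -5.51, Cer1 at -6.04, Foxa2 at -2.16, Sox9 at -5.76, the WNT targets Sp5 at -7.41 and Lgr5 at -5.16, and the ERK readouts Egr1 at -6.69 and Dusp4 at -4.43. Lin28a stood at -1.96, Mycn at -1.64, Uhrf1 at -2.99, Tex19.1 at -3.59, the imprinted Mest at -8.32 and Nnat at -3.11, and the Y-linked Eif2s3y at -6.86. Fibroblast genes were part of this, with Postn at -7.15, Col3a1 at -5.06 and the protease Mmp3 at -5.08. Higher in the NOD difference were H2-K1 at 3.00, Mlc1 at 4.52 and Gkn2 at 7.95. The NOD difference is the mean of both EpiSC-like lines, which were unlike for some of these genes. For example, the iPS line minus the ES line stood at -3.71 for T, -4.01 for Sp5, -5.55 for Egr1 and -3.26 for Fgf5. Of the 27 genes, 12 were already higher in NOD ES than in the mESM arrays, which held the least fibroblast signal, and 0 lower by limma. These were Fgf5, Egr1, Dusp4, Sp5, Gsc, Sox9, Tex19.1, Uhrf1, Mest, Postn, Col3a1 and Mmp3, so for these genes the difference may reflect the ES baseline too. With the slide as a block 0 genes passed between NOD ES and mESM, although 99.6% of the called genes kept their direction. Normexp ended the calls of Fgf5 and Postn in that comparison. For the difference between the differences, 277 genes passed with the slide as a block against 2903, with 99.966% of these in the same direction. The median SE was 0.48 against 0.36 where the call ended, and no biological explanation was tested.

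A pair of arrays lay closer to the other group than to their own. Weak signal was examined over 7883 genes well above background on all arrays. The SD to the own group was 1.47 times that to the other group for the array labelled NOD ES replicate 1. It was 4.31 times for the array labelled EpiSC iPS replicate 2, which argues against weak signal for the latter. The former was set against EpiSC iPS replicate 1 alone, on the same slide and with only 51.2% of spots well above background, so its ratio cannot decide on weak signal. The slide was argued against for the latter, as over 22985 genes its nearest array, NOD ES replicate 3 (SD 0.853), was on another slide, and its nearest slide mate was 1.38 times as far. For the former it cannot be told apart, with a ratio of 0.816 on a slide that holds every EpiSC iPS array. Of 39 bright genes that part the other NOD from the other non-NOD arrays, the array labelled EpiSC iPS replicate 2 lay on the NOD side for 89.7%, as a wrong label would need, and the array labelled NOD ES replicate 1 on the non-NOD side for 71.8%, which decides nothing. A stricter test planned before had 2 separating genes, with 0% on the non-NOD side for the array labelled NOD ES replicate 1 and 100% on the NOD side for that labelled EpiSC iPS replicate 2, too few to tell, so exchanged labels may be the cause and stay open beside a difference between cultures.

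The NOD EpiSC-like lines and NOD ES differed in 6147 genes when the 9 NOD arrays were fitted alone. Of the 84 splits of these arrays into 6 and 3, only the real 1 gave so many, the highest other giving 240. The 6 EpiSC-like arrays are passages of 2 lines, and every other split parts arrays of the same group. The gene count of the splits therefore cannot exclude chance differences between lines. For the gene lists chance is not excluded, as 14 of 84 splits, the real 1 included, called at least the real 13 lists and 2 called 16. Within slide 4, 96.2% of the called genes kept their direction, but the same arrays helped to make these calls, so this is no independent test. With the slide as a block 6138 genes still changed, which argues against the slide as the whole cause. Passage, line and culture differ with the state and stay open.

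Fibroblast genes were higher and naive markers lower in the NOD EpiSC-like lines than in NOD ES. RNA of a single feeder population as the only source of these genes in both lines was argued against. The 20 fibroblast genes differed between the lines with an SD of 1.15, or 1.84 times the median SE of 0.627. A single population stays possible if the EpiSC-like cells express some of these genes themselves, as that could give such a spread too. Dilution of unchanged ES cells by feeder RNA would lower genes that feeder cells lack by a common amount. Over genes well above background on all NOD arrays, the SD of the difference was 6.21 times the median SE for 9 naive markers. It was 2.907 times for 9 core genes, with Dppa5a at -9.58, Lin28a at -2.46 and the naive Klf2 at 0.58. Whether feeder cells lack these genes was not measured, so this spread cannot decide on dilution. List means per array bear on the iPS line. Its arrays had fibroblast means of 3.21 and 3.07 and naive means of -1.55 and -1.27 (log2). The array labelled EpiSC iPS replicate 1 had 3.45 and 3.03, and epiESM 2.63 and 3.81. These values argue against dilution by feeder RNA like theirs as the whole cause in the iPS line. Dilution as a part of the cause, or as the whole in the ES line, stays open. So do feeder cells that differ between lines, and expression of matrix genes by the EpiSC-like cells themselves. The labels give mechanical separation for these lines and preplating for ES cells, so the method differs with the state.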

How the results depend on the processing

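The analyses without both doubtful arrays, with the mESM arrays averaged and with the slide as a random block were chosen only after the results were seen. Counts of genes are given in this order: NOD EpiSC-like minus NOD ES, EpiSC minus mESM, EpiSC iPS minus EpiSC, NOD EpiSC-like minus EpiSC, NOD ES minus mESM, EpiSC iPS minus mESM, EpiSC-like iPS minus EpiSC-like ES, epiESM minus mESM, and the interaction. Of 397 alternatives to the main counts, correlations and positions, 285 stayed within 1.5 times the count or within the spread and 112 moved. The cause was not tested unless given.

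Only the NOD state comparison stayed within 1.5 times its count of 8966 in every alternative but 1, the filter on all 16 arrays, which tests fewer genes (5232). That filter also gave 3277 for EpiSC minus mESM, 3245 for EpiSC iPS minus EpiSC, 3744 between the EpiSC-like lines, 27 list calls and a position of 0.682. Quantile normalization moved no count. Normexp gave 1518, 748, 775, 33, 7, 60, 21 and 30 for the later 8 counts, a correlation of 0.481 and a position of 0.333 for EpiSC on the NOD axis, which the value table put at 0.699.

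Array weights, whose fit gave a convergence warning, moved the later 8 counts to 15301, 3000, 9792, 13039, 1235, 9071, 13094 and 11476. Fitting only the groups compared, with fewer residual degrees of freedom, gave 13819, 655 and 7351 for EpiSC minus mESM, EpiSC iPS minus EpiSC and EpiSC-like minus EpiSC, 14473 for epiESM, and by limma 0 for NOD ES minus mESM (4823 at an unadjusted p under 0.05) and 0 for EpiSC iPS minus mESM (5660). The slide as a fixed block gave 2026 for EpiSC minus mESM, 0 for NOD ES minus mESM by limma (3537 unadjusted), 2134, 78 and 277 for the last 3, and a correlation of 0.570. As a random block it gave 1221 and 1249 for the comparisons of NOD ES and EpiSC iPS with mESM.

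Leaving out both doubtful arrays raised the later 8 counts to 10620, 9735, 9561, 5995, 8600, 11729, 5746 and 8190. Averaging the mESM arrays lowered the 5 that use them to 2772, 160, 242, 103 and 1009, as fewer samples would. Both 129 cultures as 1 group gave 632, 609 and 1536 for NOD ES, EpiSC iPS and the interaction, and a correlation of 0.665. The epiESM count was 585 with no filter and 1493 with trended moderation. An adjusted p under 0.01 gave 3157, 2695, 1661, 616, 804, 3048, 166 and 1155. The correlation was 0.569 with no filter, 0.690 with the EpiSC-like ES line alone, 0.479 with the iPS line alone and 0.709 over genes called at least once. Camera with an estimated correlation called 0 list pairs (26 at an unadjusted p under 0.05), and fry called 84.

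With each array left out in turn the counts ranged from 2804 to 8092, 2455 to 7419, 1017 to 6344, 145 to 3228, 255 to 5125, 2485 to 8591, 99 to 2571 and 1015 to 4954 for the later 8, the correlation from 0.583 to 0.651 and the position of EpiSC from 0.741 to 0.848. With 1 array left in a group, it was assumed to vary like the others. The replicate numbers in the labels pair no arrays across groups, so no analysis by pair was made, and slides shared between groups were treated as a block.

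For the named genes, 6549 of 7077 alternatives gave the same call, 427 lost it, 96 gained it and 5 reversed. The reversed were Klf2 between the NOD states over all probes (-1.77), Sox2 in EpiSC iPS minus EpiSC without the doubtful arrays (-0.91), Tcstv1 there with the slide block (-0.093), and with normexp Mcpt9 in the EpiSC-like lines minus EpiSC (0.14) and Pou5f1 between the EpiSC-like lines (0.38). The slide block lost 72 calls and normexp 71. The low signal over background of some arrays, 26.3% of spots on the array labelled NOD ES replicate 1, limits what can be measured there.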

Other observations

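The values here were looked up only after the main results were seen, and none was tested against an explanation.

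The sex-linked transcripts differed between lines (log2 after scaling). Xist stood at 1.26 and 1.29 on the EpiSC-like iPS arrays and between -0.99 and -0.85 on the EpiSC-like ES arrays, against -3.10 and -2.88 in EpiSC and -4.38 and -4.28 in mESM. It was not well above background on any NOD ES array. Eif2s3y, which is Y-linked, stood at 2.60 in epiESM, 1.74 and 1.87 in EpiSC, 1.36 on the array labelled NOD ES replicate 1 and -3.18 on NOD ES replicate 2, and was not above background in mESM. It stood at -0.74 and -1.06 on the EpiSC-like iPS arrays and between -0.13 and -0.03 on the EpiSC-like ES arrays. Values of NOD ES replicate 3 and of both EpiSC iPS arrays are not listed here. The mESM and epiESM arrays, both labelled 129 ES at passage 8, thus differed in a Y-linked transcript, and the labels do not say whether they are the same line.

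The first 3 axes of a principal component analysis of all arrays held 41.9%, 18.9% and 11.1% of the variance. The array labelled EpiSC iPS replicate 1 stood at 0.445 and 0.267 on the non-NOD and NOD axes, and that labelled EpiSC iPS replicate 2 at 0.289 and -0.0388. The mESM arrays correlated at 0.991 (Pearson, all probes) with an SD of 0.20.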
